A study of Mus musculus with 12 samples.

How the data were processed

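Gene expression was measured in scraped colon mucosa of 12 bone marrow chimeric mice, 1 colon per sample. Per the labels, all recipients were wild-type C57BL/6 mice that had received bone marrow from wild-type or Muc1 knockout donors, so that only cells of blood-forming origin lacked Muc1. Treated mice had an intraperitoneal injection of azoxymethane (AOM, 12.5 mg/kg) and, from 5 days later, dextran sodium sulfate (DSS) in the drinking water: 2% for 4 days, 14 days of water, the same cycle again, and 2.5% for 5 days, with the colon taken 1 day after. The other mice were untreated. Each of the 4 groups held 3 mice, and the groups were taken from the labels as WT_untreated, KO_untreated, WT_AOMDSS and KO_AOMDSS, where WT and KO name the marrow donor. Per the labels' protocols, RNA was isolated with an RNeasy kit and labelled with Cy3 by the Quick Amp method.

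The authors deposited the scanner output of 12 single-colour Agilent mouse arrays (design 014868), extracted with Feature Extraction 10.7.3.1, per the file headers. Its values are linear spot intensities, already background-corrected by the scanner software, per the file headers, and not yet scaled between arrays. A deposited table of the whole series holds the authors' 4 group means of 2506 probes as log2 values. Set against the arrays, those values were log2 group means minus the median of each probe over the 12 arrays. The rule by which the authors chose these probes is not given in the sources used here.

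The signals were processed in R 4.3.3 with limma 3.58.1 and the package data.table (version 1.17.8). The log2 processed signal minus its 75th percentile on each array was used, over 43379 gene spots of 45018, with control spots left out and spots marked as outliers by the scanner software set to missing. Spots of a probe were averaged, which gave 41174 probes, 1936 of them with a missing value on at least 1 array. Accessions in the files were matched without versions to a table of mouse genes (assembly GRCm38.p6, used for names only). A symbol was found for 24375 probes, of 17016 genes, and 16799 probes kept the name given in the files. A probe was kept if it was well above background on all 3 arrays of at least 1 group, which 30219 probes were. Each gene was represented by the kept probe with the highest mean over the 12 arrays, which left 23614 genes, 14564 of them with a symbol and 1353 with a missing value. Below, genes named only by an accession or clone are counted as genes.

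A linear model with a mean for each group was fitted to all 12 arrays with limma, with moderated variances that followed a trend in intensity (8 residual and 4.9 prior degrees of freedom). There were 5 comparisons: treated against untreated mice with each marrow, KO against WT marrow in treated and in untreated mice, and the difference between the marrows in the treatment effect (the interaction). P values were adjusted by the Benjamini-Hochberg method within a comparison, with a threshold of 0.05. Changes are log2 differences ± SE, and n is 3 mice per group. A total of 33 gene lists of cell types, pathways and chromosomal neighbours of Muc1 were written before the data were examined, together with the groups, the tests, the rule for named genes and the main alternatives. The 32 lists with at least 5 measured members were tested with limma's camera, which sets a list against all other genes, with a preset correlation of 0.01 between genes and, as an alternative, with the correlation estimated from the arrays. The sex-linked list had 3 measured members and was not tested as a list.

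Named genes were Muc1, the 5 largest positive and 5 largest negative changes among called genes with a proper symbol whose values in the compared groups did not overlap, and up to 4 called members of each list that passed its test or had at least 3 called members. Where fewer than 10 genes passed, the 5 highest and 5 lowest moderated statistics were named as not past the threshold. For a probe not well above background on any array of a group, the fold is given as "at least N-fold". It is the mean of the brighter group against the mean, over the dimmer group's arrays, of the higher of the probe's own signal and the lowest signal among probes well above background.

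Slide and scan day were read from the files and used as batches. Each treatment and donor result was fitted again with slide as a block (6 residual degrees of freedom), and within each slide that held both groups of a comparison (23602 genes). Slide 1 held 3 WT_untreated arrays against 1 KO_untreated array, slide 2 held 1 KO_AOMDSS array against 2 KO_untreated arrays and against 1 WT_AOMDSS array, and slide 3 held 2 KO_AOMDSS against 2 WT_AOMDSS arrays. A lone array in such a fit is assumed to vary like the other groups. No slide held both WT-marrow groups or all 4 groups, so no within-slide value exists for the treatment effect with WT marrow or for the interaction.

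The alternatives were quantile normalization, normexp background correction (offset 50) of the median signals, other filters on dim probes, the mean of a gene's probes, no intensity trend, robust moderation, array weights, only the arrays compared, the replicate number, slide or scan day as a block, the estimated correlation, a 2-fold minimum, and leaving out each array. The within-slide fits, slides 1 and 2 alone, slide block with array weights, and genes with a symbol only were added after seeing the data, as was the use of the median signal for normexp, since the files hold no mean signal. The fits were tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold in each comparison. At 4-fold, the fit called 30% of them for the treatment effect with WT marrow, 35% with KO marrow, 34% for the donors in treated mice, 28% for the donors in untreated mice and 3% for the interaction, with 0 to 4 false calls among 23614 genes. These shares with slide as a block were 0%, 23%, 56%, 12% and 0%. At 2-fold, the shares were 3%, 3%, 2%, 2% and 0%, and with slide as a block 0%, 0%, 6%, 0% and 0%. The simulated noise was independent between genes and arrays. A difference shared by the arrays of a slide was simulated only for the fit with slide as a block. The false calls without the block therefore do not show how that fit behaves on arrays that differ by slide. Values of 2 list genes are not reported here, and the counts and list medians include them. The number of arrays, 3 per group, limits the precision.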

Results

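The data were 12 single-colour arrays of colon mucosa, 1 mouse per array, from wild-type mice carrying wild-type marrow (WT marrow) or marrow lacking Muc1, the gene of a membrane-bound mucin (KO marrow). Mice of each kind were untreated or had received AOM, a colon carcinogen, with cycles of DSS, which injures the colon lining. The 75th percentile of the signal was 332 to 767.8 units on the arrays other than WT_AOMDSS 3, where it was 153.2. Between 58.44% and 78.72% of gene probes per array were well above background, and 0 spots were saturated.

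The arrays lay on 3 slides of 4. Slide 1 held the 3 WT_untreated mice and KO_untreated 1. Slide 2 held KO_untreated 2 and 3, WT_AOMDSS 3 and KO_AOMDSS 3. Slide 3, scanned on the later of 2 days, held the other 4 treated mice and had 491 to 767 non-uniform spots per array against 4 to 51 elsewhere. Taken alone, slide accounted for 57.7% of the variance and group for 49.9%. Arrays of the same group correlated at 0.96 to 0.987 within a slide and at 0.888 to 0.967 between slides, across genes. Between arrays of the same group on different slides, limma called 2662 genes for untreated KO marrow (2636 higher on slide 1), 43 for treated KO marrow and 7856 for treated WT marrow, the last against the dim array WT_AOMDSS 3.

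**Figure D1:**
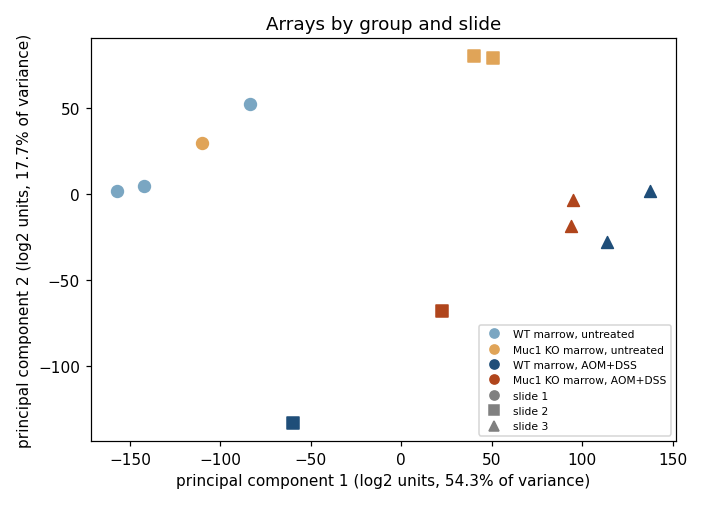
Position of each array on the first and second principal components of the log2 signals (log2 units), which hold 54.3% and 17.7% of the variance. Colour marks the group and marker shape the slide. The 4 arrays of slide 1 lie at -156.9 to -83.7 on the first component and the 4 of slide 3 at 94.1 to 137.3, while WT_AOMDSS 3 lies at -59.9.

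Muc1 was measured in every sample. Only cells of blood-forming origin lacked it, and where the probes lie relative to the deleted part is not given in the sources used here, so its level in whole mucosa checks no label. Its log2 signal relative to the array's 75th percentile was -1.5, -1.72 and -2.25 in WT_untreated 1 to 3, -2.12, -2.90 and -3.80 in KO_untreated 1 to 3, -2.17, -1.47 and -3.53 in WT_AOMDSS 1 to 3, and -2.30, -0.99 and -2.41 in KO_AOMDSS 1 to 3. The probe was well above background on all 12 arrays. The group means were -1.82 ± 0.38, -2.94 ± 0.84, -2.39 ± 1.04 and -1.90 ± 0.79 (SD, n = 3), and Muc1 passed in no comparison of limma, with an adjusted p of 0.424 or more. The 2 probes of Muc1 disagreed: the mean of both gave 0.52 for the treatment effect with WT marrow and 0.05 for KO against WT marrow without treatment, against -0.57 and -1.11 with the brighter probe.

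The comparison of treated with untreated mice carrying WT marrow asked what the AOM and DSS protocol did to the mucosa. The 5 largest rises of single genes were those of neutrophil genes, inflammatory signals and osteopontin. S100a8 and S100a9, whose products form the neutrophil protein calprotectin, rose by 9.57 ± 0.85 (760-fold, adjusted p = 0.000186 in limma) and 8.37 ± 0.63 (331-fold, adjusted p = 3.84e-05). Il1b, an inflammatory cytokine, rose 145-fold (7.18 ± 0.65), Cxcl5, a neutrophil attractant, 136-fold (7.09 ± 0.66), and Spp1, which encodes osteopontin, at least 60.3-fold (6.94 ± 0.88). S100a8 was well above background on 1 of 3 untreated arrays and Cxcl5 on 2. Blocked by slide, these changes were 7.30 for S100a8 (adjusted p = 0.0672), 9.85 for S100a9 (0.00311), 9.87 for Il1b (4.72e-05), 7.27 for Cxcl5 (0.0202) and 8.73 for Spp1 (0.0213).

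Among the largest falls, Dbp, a transcription factor under control of the circadian clock, changed by -5.68 ± 0.49 on the log2 scale (51.2-fold lower, adjusted p = 0.000151), and by -4.97 with slide as a block (adjusted p = 0.0158). Nrxn3, a neuronal adhesion gene, was at least 19.1-fold lower (-6.19 ± 1.34), Sptb, which encodes a spectrin of the red cell membrane, at least 31.7-fold lower (-5.91 ± 1.11), Slc22a2, an organic cation transporter, at least 13.6-fold lower (-5.56 ± 1.10), and Nt5c1b, a nucleotidase, at least 23.9-fold lower (-5.49 ± 1.22), with adjusted p values of 0.0102 to 0.0186. The changes with slide as a block were 0.32 for Nrxn3, -1.24 for Sptb, -1.08 for Slc22a2 and 0.10 for Nt5c1b, none past the threshold (adjusted p of 0.596 to 0.976). With normexp, Slc22a2 was at 0.22.

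Of 23614 genes, 3239 passed, 844 higher and 2395 lower in treated mice (26.1% higher), 3033 of them by at least 2-fold. The median change of all genes was -0.244. Quantile normalization gave a median of 0.06 and 4683 calls, 48.8% of them higher, and normexp gave 0.40 and 834 calls, 36.7% higher. With slide as a block 128 genes passed (111 higher and 17 lower), 73 of them among the 3239. For this comparison that fit ties the WT_untreated arrays to the other slides through KO_untreated 1 alone, the remaining array of slide 1. All slide-blocked values of the treatment effect with WT marrow therefore depend on that mouse and on the KO-marrow arrays. That fit moved the median change of all genes to 0.47. In it 99.5% of the higher and 57.0% of the lower calls kept their sign, and 93.6% and 78.2% lay on the same side of its median. Single arrays moved the count: it was 471 without WT_untreated 1, 508 without WT_untreated 2, 1876 without WT_untreated 3, 483 without WT_AOMDSS 1, 1231 without WT_AOMDSS 2, 7617 without WT_AOMDSS 3 and 2066 without KO_AOMDSS 1.

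Inflammatory and myeloid gene lists rose with WT marrow. Of the chemokines, 10 of 17 measured rose (11 adjusted over the list alone), among them Cxcl3 (6.15, at least 18.6-fold), Ccl3 (5.89, at least 50.1-fold) and Cxcl2 (5.37, at least 27.3-fold), with a list median of 3.23 (adjusted p = 1.17e-10 by camera). Of the inflammatory cytokines and enzymes, 7 of 15 rose (10 rose and 1 fell adjusted over the list alone), including Ptgs2, the inducible cyclooxygenase (4.31, at least 7.72-fold), Il22 (4.07, at least 3.39-fold, well above background on 2 treated arrays) and Ifng (3.51), with a median of 1.76 (adjusted p = 4.53e-07). Of the suppressive myeloid mediators, 8 of 18 rose (12 rose and 1 fell adjusted over the list alone), with a median of 1.90 (adjusted p = 2.9e-10), led by S100a8, S100a9, Ptgs2 and Arg1 (4.24 ± 0.63), which encodes arginase. S100a8 and S100a9 also stand on the neutrophil list and Ptgs2 on the cytokine list. Of the neutrophil markers, 7 of 16 rose (7 adjusted over the list alone), among them Clec4e (5.90, at least 58.6-fold) and Retnlg (5.33, at least 22.3-fold). The neutrophil median was 1.89 (adjusted p = 2.68e-08, but adjusted p = 0.0627 with an estimated correlation). Of the monocyte and macrophage markers, 8 of 16 rose (10 rose and 1 fell adjusted over the list alone), among them Mpeg1 (2.57 ± 0.31), Msr1, Itgam and C1qa, with a median of 1.76 (adjusted p = 1.62e-06, but adjusted p = 0.0901 with an estimated correlation). The slide-blocked medians of these 5 lists were 3.00, 2.91, 2.37, 4.04 and 2.16, each past the threshold in the same direction. With the block 5 chemokines, 2 cytokine genes, 2 suppressive mediators, 3 neutrophil markers and 1 monocyte marker (Mpeg1) passed in limma, and S100a8, Ptgs2, Il22, Ifng, Arg1, Msr1, Itgam and C1qa did not. In that fit 4 of the 5 lists also passed with an estimated correlation, the exception being monocyte and macrophage markers (adjusted p = 0.256).

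Antimicrobial and tissue remodelling genes rose as well. Of the antimicrobial and acute-phase genes, 7 of 18 rose (9 adjusted over the list alone), among them the bactericidal lectins Reg3b (6.77 ± 1.43) and Reg3g (6.39 ± 1.13), the protease inhibitor Slpi (4.61 ± 0.57) and Hp, haptoglobin (5.29 ± 1.29), with a median of 0.98 (adjusted p = 1.25e-06). Of the matrix proteases and their inhibitors, 6 of 15 rose (7 adjusted over the list alone), among them the metalloproteinases Mmp3 (5.13 ± 0.99, well above background on 1 untreated array), Mmp13 (4.43 ± 0.64) and Mmp7 (2.55) and the urokinase receptor Plaur (2.63). Their median was 1.66 (adjusted p = 1.7e-06, but adjusted p = 0.106 with an estimated correlation). Of the fibroblast and matrix genes, 3 of 18 rose (4 adjusted over the list alone), namely Spp1, Pdgfra (2.50, at least 3.22-fold, well above background on 2 treated arrays) and Col1a1 (2.17, with overlapping values), with a median of 1.18 (adjusted p = 1.34e-05, but adjusted p = 0.319 with an estimated correlation). Pdgfra was at -0.07 when its probes were averaged. The fibroblast list median was 1.90 in WT_AOMDSS 2, against -0.20 and 0.57 in the other treated mice with WT marrow and 0.69 in WT_untreated 2. Without WT_AOMDSS 2 the change was 0.70, still past the threshold. The slide-blocked medians of these 3 lists were 1.48, 2.75 and 1.53, each past the threshold. With the block Slpi was the 1 antimicrobial gene and Spp1 the 1 fibroblast gene past the threshold in limma, while 3 proteases passed, Mmp7 among them but neither Mmp3, Mmp13 nor Plaur. In that fit none of the 3 lists passed with an estimated correlation (adjusted p = 0.256, 0.118 and 0.62).

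The absorptive colonocyte, xenobiotic and tuft lists fell with WT marrow. Of the absorptive colonocyte markers, 8 of 18 fell (9 adjusted over the list alone), among them the chloride exchanger Slc26a3 (-2.38 ± 0.37, adjusted p = 0.00514), the guanylin gene Guca2a (-2.84 ± 0.51), Tmigd1 (-2.97) and the bile acid exporter subunit Slc51a (-3.56, at least 10.1-fold lower, 0.64 with normexp). Their median was -1.13 (adjusted p = 0.000449). Of the xenobiotic metabolism genes, 11 of 16 fell (11 adjusted over the list alone), among them Ugt2b5 (-3.90, well above background on 1 treated array), Ugt1a1 (-2.28, on 2 treated arrays, 0.22 with normexp), the sulfotransferase Sult1a1 (-2.23 ± 0.33, adjusted p = 0.00391) and Cyp2s1 (-2.03), with a median of -1.53 (adjusted p = 8.67e-06). Of the tuft cell markers, 4 of 10 fell (8 adjusted over the list alone), namely Rgs13 (-2.92 ± 0.47), the taste channel Trpm5 (-2.12), Alox5 (-1.85) and Dclk1 (-1.66), with a median of -1.76 (adjusted p = 0.00443, but adjusted p = 0.319 with an estimated correlation). The slide-blocked medians were -1.42, -1.5 and -1.22, each past the threshold. With the block 0 members of these 3 lists passed in limma, Slc26a3 being at -1.97 (adjusted p = 0.116), Sult1a1 at -2.57 (adjusted p = 0.0623) and Rgs13 at -2.91 (adjusted p = 0.141). The tuft call was lost there with an estimated correlation (adjusted p = 0.256).

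The remaining 4 lists to shift with WT marrow lost the call with an estimated correlation, and 0 of their members passed in limma with slide as a block. Of the proliferation genes, 2 of 23 rose, the replication genes Mcm3 (1.65) and Rrm2 (1.54) (7 adjusted over the list alone), with a median of 1.04 (adjusted p = 9.39e-09, but adjusted p = 0.236 with an estimated correlation) and of 1.42 with slide as a block, past the threshold but not with an estimated correlation (adjusted p = 0.591). Of the interferon-stimulated genes, Oas2 (2.27) rose, 1 of 22 (0 adjusted over the list alone), with a median of 0.36 (adjusted p = 0.00644, but adjusted p = 0.558 with an estimated correlation). Of the endoplasmic reticulum stress genes, 3 of 15 rose (3 adjusted over the list alone), the chaperone genes Hsp90b1 (0.96) and Hspa5 (0.85) and Creld2 (1.25), with a median of 0.06 (adjusted p = 0.048, but adjusted p = 0.232 with an estimated correlation). With slide as a block these 2 lists had medians of 0.50 and 0.52, while the test, set against all other genes, leaned down and did not pass. Of the red blood cell markers, 3 of 6 fell (4 adjusted over the list alone), among them Hba-a1 (-2.54, with overlapping values) and Slc4a1 (-2.17, 0.11 with slide as a block). Their median was -2.18 (adjusted p = 0.0254, but adjusted p = 0.236 with an estimated correlation), and -0.16 with slide as a block (adjusted p = 0.262). The calls that held with an estimated correlation were those of the chemokines, cytokines, suppressive myeloid mediators, antimicrobial genes, colonocyte markers and xenobiotic genes. Of these 6, the antimicrobial list did not pass that test with slide as a block.

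The other 17 lists did not pass with WT marrow, though some had several changed members. With slide as a block 5 of these passed: goblet cell genes (-0.71, adjusted p = 0.000173), fatty acid oxidation genes (-0.46, adjusted p = 0.00293), B and plasma cell markers (1.93, adjusted p = 0.0102), mast cell markers (1.58, adjusted p = 0.0418) and stem cell and Wnt target genes (0.85, adjusted p = 0.0418). Of the members of all 17, Hdc and Ly6d alone passed in limma in that fit. In that fit the calls of goblet cell and fatty acid oxidation genes held with an estimated correlation (adjusted p = 0.0459 and 0.00564). Those of the B and plasma cell, mast cell and stem cell lists did not (adjusted p = 0.493, 0.234 and 0.0538). Of the mast cell markers, Hdc, the histamine-forming enzyme (4.84 ± 0.91), Mcpt1 (3.00 ± 0.42), Mcpt2 (2.91, at least 4.47-fold, well above background on 2 treated arrays) and Mcpt4 (2.56) rose, while the tryptase Tpsb2 (-3.48 ± 0.88, 0.42 with slide as a block) and Cma1 (-1.87) fell, with a list median of 0.27 (adjusted p = 0.0748). Of the antigen presentation and dendritic cell markers, Itgax (2.81 ± 0.36) and Cd86 (1.95, at least 2.71-fold, on 2 treated arrays) rose and Flt3 (-2.71, 0.41 blocked) and Zbtb46 (-2.33, 0.58 blocked) fell, with a median of 0.24 (adjusted p = 0.21). Of the squamous epithelium markers, Ly6d (4.19 ± 0.71, 7.16 blocked, adjusted p = 0.0158) and Sfn (0.94) rose and Lor (-1.35, 0.12 with normexp) fell, with a median of -0.52 and a test that leaned up (adjusted p = 0.701). Of the fatty acid oxidation genes, the transporter Slc16a1 (-2.20), the lipid sensor Ppara (-1.73) and Acaa2 (-1.02) fell, with a median of -0.39 (adjusted p = 0.25). The medians were -0.77 for T and NK cell markers (adjusted p = 0.49), 0.05 for B and plasma cell markers (mean -0.08, adjusted p = 0.368), 0.27 for enteroendocrine markers (adjusted p = 0.0655), -0.47 for goblet cell genes (adjusted p = 0.424) and 0.18 for stem cell and Wnt target genes (adjusted p = 0.12). They were 0.31 for smooth muscle (adjusted p = 0.21), -1.12 for enteric neuron and glia (adjusted p = 0.161), -2.04 for adipocyte markers (adjusted p = 0.0884), 0.08 for hypoxia and glycolysis genes (adjusted p = 0.0909) and 0.17 for the chromosomal neighbours of Muc1 (mean -0.10, adjusted p = 0.301). For eosinophil markers (-1.31, adjusted p = 0.933), mucins (-0.57, adjusted p = 0.948) and endothelial markers (-0.49, adjusted p = 0.79) the median was negative while the test leaned up.

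**Figure D2:**
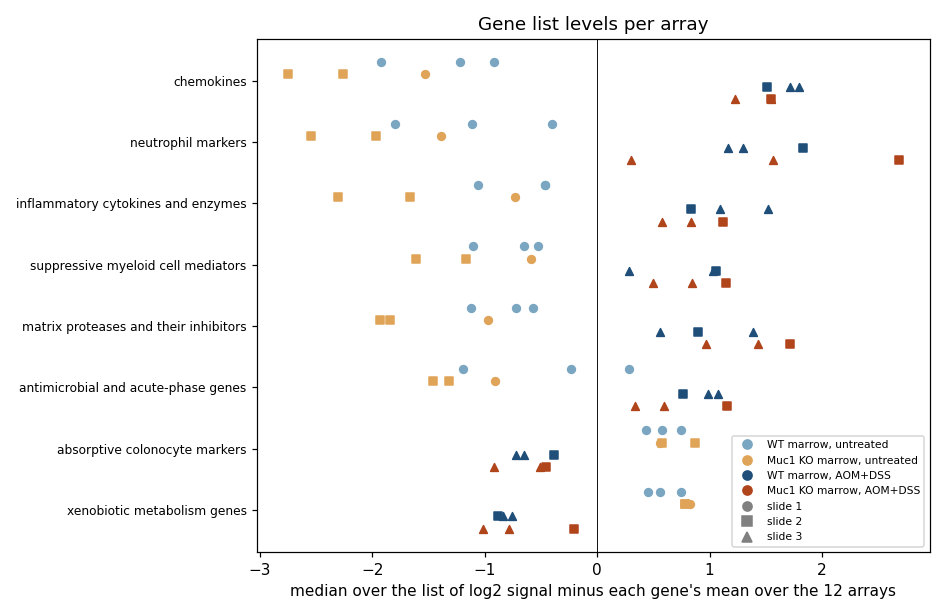
Median of each gene list on each array, as the log2 signal minus each gene's mean over the 12 arrays, for 8 lists, with colour for the group and marker shape for the slide. The chemokine, neutrophil, cytokine, suppressive myeloid, protease and antimicrobial lists, whose medians rose by 0.98 to 3.23 with WT marrow and by 2.17 to 3.85 with KO marrow, lie higher in treated mice, and the colonocyte and xenobiotic lists lie lower.

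The same comparison in mice carrying KO marrow gave the response when blood-forming cells lacked Muc1. The 5 largest rises of single genes were those of antimicrobial and neutrophil genes and of Spp1. Reg3b rose by 10.22 ± 1.43 (1190-fold, adjusted p = 0.00214 in limma), Reg3g by 7.60 ± 1.13 (194-fold), S100a8 by 8.32 ± 0.85 (318-fold, well above background on 1 untreated array), S100a9 by 7.94 ± 0.63 (246-fold, adjusted p = 7.44e-05) and Spp1 by 8.06 ± 0.88 (at least 81.8-fold). Dbp (-6.14 ± 0.49, 70.4-fold lower, adjusted p = 7.44e-05) and Nr1d1, a repressor of the circadian clock (-4.69 ± 0.54, 25.7-fold lower), were among the largest falls. Slc30a10, a manganese exporter (-5.72 ± 0.98), Higd1c (-5.48 ± 0.80, at least 17.1-fold lower) and Nat8f5 (-5.22 ± 0.71) were the others, with Slc30a10 and Nat8f5 well above background on 1 treated array. Blocked by slide, the changes were 10.79, 8.66, 7.30, 9.11 and 9.47 for the genes that rose and -5.32, -4.56, -3.92, -4.63 and -4.80 for those that fell, all past the threshold. Within slide 2, the slide that held both groups, with KO_AOMDSS 3 as the lone treated array, the rises were 10.73, 9.02, 7.80, 9.0 and 10.03. The falls were -5.13, -4.86, -3.45, -5.15 and -3.81, and all 10 changes but that of Slc30a10 (adjusted p = 0.118) passed.

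With KO marrow 744 genes passed, 436 higher and 308 lower (58.6% higher), 722 of them by at least 2-fold, with a median change of all genes of -0.113. Quantile normalization gave a median of 0.02 and 865 calls, 70.4% of them higher, and normexp a median of 0.24. A total of 1721 genes passed with slide as a block (1100 higher and 621 lower), 542 of them among the 744, with a median change of all genes of 0.444, and all 744 kept their sign. Within slide 2, 982 genes passed (649 higher and 333 lower). The count was 300 without KO_untreated 2, 247 without KO_untreated 3, 1246 without WT_AOMDSS 3, 380 without KO_AOMDSS 1, 407 without KO_AOMDSS 2 and 494 without KO_AOMDSS 3.

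Inflammatory, myeloid and remodelling lists rose with KO marrow. Of the chemokines 11 of 17 rose (12 adjusted over the list alone), among them Ccl3 (7.26, at least 56.8-fold), Ccl4 (6.54), Cxcl3 (6.53, at least 20.3-fold) and Cxcl2 (5.98, at least 19.5-fold), with a median of 3.85 (adjusted p = 2.25e-19 by camera). Of the neutrophil markers 8 of 16 rose (10 adjusted over the list alone), including Retnlg (5.96, at least 28.3-fold) and Clec4e (5.70), with a median of 3.57 (adjusted p = 7.55e-15). Of the cytokines and enzymes 7 of 15 rose (11 adjusted over the list alone), including Il1b (7.26 ± 0.65), Ptgs2 (4.93, at least 8.09-fold), Il6 (3.76, at least 5.28-fold) and Ifng (3.76), with a median of 2.77 (adjusted p = 8.08e-13). Of the suppressive myeloid mediators 10 of 18 rose (12 adjusted over the list alone), including Arg1 (5.23 ± 0.63), with a median of 2.37 (adjusted p = 7.46e-18). Of the monocyte and macrophage markers 8 of 16 rose (12 rose and 1 fell adjusted over the list alone), including Fcgr1 (3.72 ± 0.45), Mpeg1 (3.22 ± 0.31), C1qc and Itgam, with a median of 2.26 (adjusted p = 2.78e-13). Of the antimicrobial genes 8 of 18 rose (11 adjusted over the list alone), including Slpi (6.51 ± 0.57) and Hp (5.74), with a median of 2.17 (adjusted p = 3.01e-12). Of the proteases 9 of 15 rose (12 adjusted over the list alone), including Mmp3 (7.38, at least 58.4-fold), Mmp13 (6.23 ± 0.64), Mmp10 (4.12) and the plasminogen activator Plat (3.98 ± 0.47), with a median of 3.32 (adjusted p = 5.62e-16). Of the fibroblast and matrix genes 6 of 18 rose (14 adjusted over the list alone), including Pdgfra (4.03, well above background on 1 untreated array), Tnc (3.86) and Col1a1 (3.32 ± 0.59), with a median of 2.09 (adjusted p = 2.12e-15).

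Of the colonocyte markers 6 of 18 fell with KO marrow (9 adjusted over the list alone), including Slc26a3 (-3.04 ± 0.37, adjusted p = 0.000888), the sodium exchangers Slc9a3 (-2.39) and Slc9a2 (-2.11) and the carbonic anhydrase Car4 (-1.98 ± 0.28), with a median of -1.31 (adjusted p = 1.48e-08). Of the xenobiotic genes 8 of 16 fell (13 adjusted over the list alone), including Sult1a1 (-2.81 ± 0.33), Gstm3 (-2.34), the efflux pump Abcb1a (-2.25) and Cyp3a13 (-1.81), with a median of -1.42 (adjusted p = 1.02e-14). Of the fatty acid oxidation genes Ppara (-1.37) and Acaa2 (-1.16) fell, 2 of 19 (5 adjusted over the list alone), with a median of -0.47 (adjusted p = 0.000141). These 3 lists and the 8 that rose, above, held with an estimated correlation. All 11 also passed in the same direction with slide as a block, and 9 of them also with an estimated correlation, the exceptions being monocyte and macrophage markers (adjusted p = 0.138) and fibroblast and matrix genes (adjusted p = 0.344). Within slide 2 those 9 lists had medians of 3.57 (chemokines), 4.82 (neutrophil markers), 3.40 (cytokines), 2.60 (suppressive mediators), 2.91 (antimicrobial genes), 3.96 (proteases), -1.02 (colonocyte markers), -1.05 (xenobiotic genes) and -0.41 (fatty acid oxidation), each past the threshold. With slide as a block Ifng (adjusted p = 0.0536), Ppara (adjusted p = 0.0839) and Acaa2 (adjusted p = 0.108) were not past it in limma.

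A further 6 lists rose with KO marrow by the preset correlation and lost the call with an estimated one. Of the mast cell markers, Hdc (5.53), Mcpt2 (3.42, at least 4.59-fold), Mcpt1 (3.34) and Mcpt4 (3.30) rose, 4 of 10 (4 adjusted over the list alone), with a median of 0.71 (adjusted p = 0.00152, but adjusted p = 0.0711 with an estimated correlation). Of the interferon-stimulated genes 2 of 22 rose, among them Oas2 (2.77) (7 adjusted over the list alone), with a median of 1.06 (adjusted p = 1.18e-07, but adjusted p = 0.193 with an estimated correlation). Of the dendritic cell and antigen presentation markers Itgax (2.34) rose, 1 of 14 (3 adjusted over the list alone), with a median of 1.93 (adjusted p = 1.23e-05, but adjusted p = 0.121 with an estimated correlation). Of the B and plasma cell markers Jchain, the joining chain of secreted antibodies (2.63 ± 0.41), rose, 1 of 15 (4 adjusted over the list alone), with a median of 0.69 (adjusted p = 0.0122, but adjusted p = 0.511 with an estimated correlation). Of the enteroendocrine markers Tac1, which encodes substance P (4.49 ± 0.76), rose, 1 of 15 (2 adjusted over the list alone), with a median of 0.44 (adjusted p = 0.0193, but adjusted p = 0.227 with an estimated correlation). Of the 23 proliferation genes 0 rose by limma, over all genes or adjusted over the list alone, with a median of 0.49 (adjusted p = 0.000458, but adjusted p = 0.511 with an estimated correlation). Blocked by slide, Oas2 was not past the threshold (adjusted p = 0.0629), and the interferon (adjusted p = 0.213), enteroendocrine (adjusted p = 0.813) and proliferation lists (adjusted p = 0.12) did not pass. The mast cell, dendritic cell and B cell lists passed in that fit, but not with an estimated correlation (adjusted p = 0.0872, 0.478 and 0.485). The other 15 lists had adjusted p values of 0.102 to 0.91. Of these, smooth muscle markers passed with slide as a block (-0.69, adjusted p = 0.0216, but adjusted p = 0.485 with an estimated correlation). Among them the median and the test differed in sign for eosinophil (-0.08), smooth muscle (-0.15), enteric neuron (-0.13), squamous (-0.16) and hypoxia (-0.10) lists, and the mean did so for goblet cell genes (median 0.11, mean -0.13) and neighbours of Muc1 (median 0.05, mean -0.03).

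**Figure D3:**
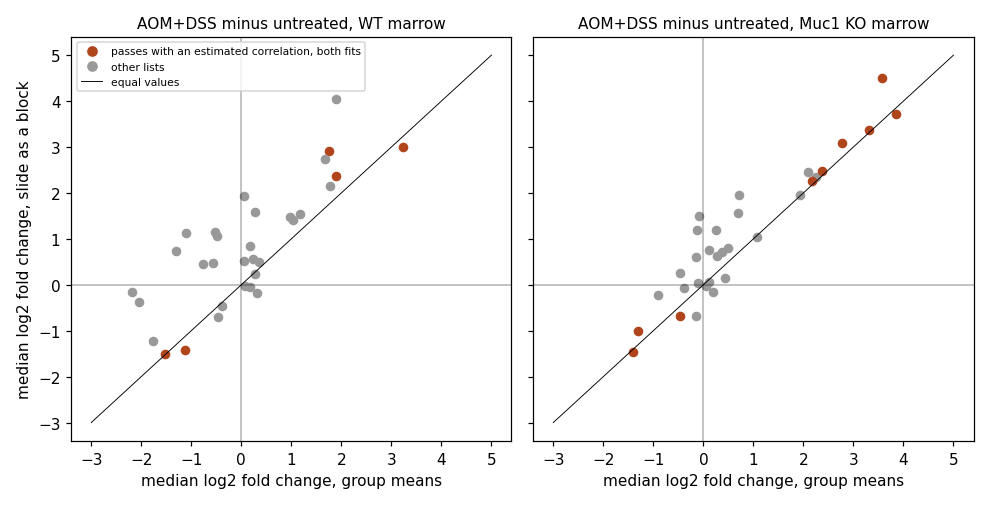
Median log2 change of each of the 32 gene lists after AOM and DSS (horizontal axis) against the median with slide as a block (vertical axis), for WT and KO marrow. Lists in orange pass with an estimated correlation in both fits, 5 with WT marrow and 9 with KO marrow, other lists are grey, and the line marks equal values.

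The responses of the 2 kinds of chimera were set side by side. Across genes the log2 changes had a Pearson r of 0.718 (leave-one-array-out SE 0.28), and genes are not independent replicates. Both comparisons called 560 genes, all in the same direction: 325 higher, among them Il1b, Cxcl2, Ccl3 and Mmp13, and 235 lower, among them Dbp, Slc26a3 and Sult1a1. Independent lists of the same lengths would share 15.6 higher and 31.2 lower genes. The comparisons share no array but do share slides: with slide as a block r was 0.879, against 0.488 by chance in that fit, and 127 genes were called in both. The shared count was 289 without WT_untreated 1, 330 without WT_untreated 2, 343 without WT_untreated 3, 274 without KO_untreated 2, 234 without KO_untreated 3, 251 without WT_AOMDSS 1, 910 without WT_AOMDSS 3, 309 without KO_AOMDSS 1 and 331 without KO_AOMDSS 2. Without KO_untreated 1 r was 0.461.

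The comparison of KO with WT marrow in treated mice asked what the loss of Muc1 in blood-forming cells changed during the disease protocol. No single gene passed. The highest statistics were those of Klk1b4, a kallikrein (1.04 ± 0.27), Sult1c2 (0.85), Sval1 (0.80), Gipc2 (0.81) and Tspan13 (0.92), and the lowest those of the antioxidant enzyme Nqo1 (-0.80), the cochaperones Chordc1 (-0.60) and Bag2 (-0.98), Slc5a9 (-0.71) and Ngdn (-0.77), each with an adjusted p of 1 in limma, also with slide as a block. Klk1b4 was at 1.69 within slide 2 (adjusted p = 0.0432, 1 array against 1) and at 0.72 within slide 3 (adjusted p = 0.981). Of 23614 genes 0 passed in limma, 189 had an unadjusted p under 0.05, and with slide as a block 0 passed and 674 had such a p. Within slide 2, where KO_AOMDSS 3 stands alone against the dim array WT_AOMDSS 3 and the spread comes from the other groups, 562 genes passed (419 higher and 143 lower, 4243 at an unadjusted p under 0.05), and within slide 3, 0 passed in limma (1027 at an unadjusted p under 0.05). With slides 1 and 2 alone 330 passed, and in the other fits 0, the median of all genes being -0.015, or -0.43 with normexp.

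By camera 9 lists differed between the donors in treated mice, with no member past the threshold in any of them. Goblet cell genes, such as the mucus genes Agr2 (0.56 ± 0.25), Tff3 (0.59) and Zg16 (0.55), were higher with KO marrow (median 0.37, adjusted p = 0.000185), and this call alone held with an estimated correlation. Matrix proteases (0.73, adjusted p = 5.43e-05, but adjusted p = 0.49 with an estimated correlation) and enteroendocrine markers (0.39, adjusted p = 0.000429, but adjusted p = 0.178 with an estimated correlation) were higher. So were interferon-stimulated genes (0.36, adjusted p = 0.00235), fibroblast and matrix genes (0.50, adjusted p = 0.00786) and tuft cell markers (0.34, adjusted p = 0.0414), each with adjusted p = 0.756 with an estimated correlation. Proliferation genes (-0.45, adjusted p = 4.6e-07) and smooth muscle markers (-1.42, adjusted p = 0.00199) were lower, both with adjusted p = 0.637 with an estimated correlation, and so were adipocyte markers (-0.59, adjusted p = 0.0414, but adjusted p = 0.756 with an estimated correlation). The smooth muscle difference rests on WT_AOMDSS 2, whose list median was 2.41 against -1.13 and -0.72 in the other treated mice with WT marrow. Without it the difference was 0.41, and that of adipocyte markers was -0.18, the test turning (WT_AOMDSS 2 at 0.84 against -1.23 and -0.004). The difference of interferon-stimulated genes rests on KO_AOMDSS 2 (1.90 against -0.10 and 0.28) and was -0.18 without it. Of the 9 lists, 8 lost the call or turned without at least 1 array, proliferation genes being the exception (-0.17 without WT_AOMDSS 3). With normexp 10 lists passed, 10 higher and 0 lower, against 6 higher and 3 lower here. Of the 9, 7 passed with slide as a block, the tuft and adipocyte lists not (both at adjusted p = 0.0894), and 0 passed with an estimated correlation. Within slides 2 and 3 the medians were 0.90 and 0.20 for goblet cell genes, 1.5 and 0.36 for proteases, -1.21 and -0.08 for proliferation genes, 1.43 and -0.06 for fibroblast genes, -0.15 and 0.62 for interferon-stimulated genes and 0.25 and -1.14 for smooth muscle markers, and no list passed within both slides. Without WT_AOMDSS 3, 4 lists passed. Chemokines (-0.15, mean 0.02, adjusted p = 0.854), neutrophil markers (-0.12, adjusted p = 0.247) and suppressive myeloid mediators (-0.09, adjusted p = 0.741) did not differ past the threshold. For the fits within slides, list results are given with the preset correlation only, not with an estimated one. Within slide 3, with 2 mice on each side, neutrophil markers (-0.34, adjusted p = 0.0302 by camera) and inflammatory cytokines (-0.43, adjusted p = 0.0376) were lower with KO marrow. Within slide 2 they were at 0.16 and 0.63, not past the threshold.

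The comparison of KO with WT marrow in untreated mice gave the baseline. No single gene passed. The highest statistics were those of the heat shock genes Hsph1 (1.39 ± 0.23), Chordc1 (0.84) and Hspa8 (0.81), of Ggh (0.89) and of the kinase gene Sgk1 (1.75 ± 0.50), and the lowest those of Fam110a (-2.83 ± 0.47), the receptor subunit Fcer1g (-1.64 ± 0.33), Ggt5 (-2.84, well above background on 2 KO-marrow arrays), Olfr805 (-4.65, on 1) and Olfr218 (-3.80, on 2), each with an adjusted p of 0.403 in limma. With slide as a block, which is also the value within slide 1 with KO_untreated 1 as its lone KO-marrow array, Hsph1 was at 1.51 and Fam110a at -2.00, with an adjusted p of 1. Of 23614 genes 0 passed in limma, with 2902 at an unadjusted p under 0.05. Blocked by slide, 0 passed with 314, and within slide 1, 0 passed in limma with 542. Without KO_untreated 1, the KO-marrow array on the slide of the WT-marrow arrays, 1682 genes passed, 16 higher and 1666 lower. Normexp called Fam110a (-2.66, adjusted p = 0.0119) and AK016682 (-2.73, adjusted p = 0.0303), array weights called 10606, and the other fits 0.

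By camera 8 lists differed between the donors in untreated mice, with no member past the threshold. Antigen presentation and dendritic cell markers (median -1.64), T and NK cell markers (-0.99) and adipocyte markers (-2.35) were lower with KO marrow, each with adjusted p = 0.00205, but adjusted p = 0.421 with an estimated correlation. Their slide-blocked medians were -0.40, -0.39 and -1.36, each past the threshold but not with an estimated correlation (adjusted p = 0.672, 0.78 and 0.476). The slide-blocked difference sets KO_untreated 1 alone against the WT_untreated arrays, so the fit within slide 1 repeats it and adds no further support. The adipocyte median was 3.83 in WT_untreated 2 against 0.80 and 0.44 in the other untreated mice with WT marrow, and the difference was -1.24 without it, still past the threshold. That array was also the highest of the untreated ones for smooth muscle (1.26) and fibroblast and matrix genes (0.69). Antigen presentation markers were at -1.06 without WT_untreated 1, and enteroendocrine and endoplasmic reticulum stress lists each lost the call without at least 1 array. Enteric neuron and glia markers were lower (-1.38, adjusted p = 0.02, but adjusted p = 0.613 with an estimated correlation), with -0.12 with slide as a block (adjusted p = 0.688). Fatty acid oxidation genes were higher (0.21, adjusted p = 0.00205), the list call that held with an estimated correlation, with 0.34 with slide as a block (adjusted p = 0.068). Endoplasmic reticulum stress genes (0.22, adjusted p = 0.02, but adjusted p = 0.398 with an estimated correlation) were higher, also with slide as a block (0.22, adjusted p = 0.0484). Enteroendocrine markers (0.56, adjusted p = 0.0326) and xenobiotic genes (0.24, adjusted p = 0.00539) were higher, both with adjusted p = 0.421 with an estimated correlation, and did not pass with slide as a block (adjusted p = 0.0863 and 0.365). A further 4 lists were lower with slide as a block, tuft cell markers (-0.73), antimicrobial genes (-0.27), fibroblast and matrix genes (-0.48) and mast cell markers (-0.42). The slide-blocked values of this comparison describe 1 KO-marrow mouse, and camera does not measure the spread between such mice. In that fit 0 lists passed with an estimated correlation. With quantile normalization 3 lists passed, 0 higher and 3 lower. Without WT_untreated 1, 16 lists passed, and without WT_untreated 3, 13.

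The interaction asked whether the treatment effect differed between the marrows. No single gene passed. The highest statistics were those of Fam110a (2.91 ± 0.67), Olfr805 (4.94), Olfr218 (3.83), the adenosine receptor Adora3 (3.38) and Fstl4 (2.57), and the lowest those of Chordc1 (-1.44 ± 0.29), Hsph1 (-1.44 ± 0.33), Hspa8 (-1.07), the peroxiredoxin Prdx1 (-1.07) and the chaperonin subunit Cct8 (-1.05), each with an adjusted p of 0.902 in limma. Positive values mean a higher change with KO marrow. Of 23614 genes 0 passed in limma, with 799 at an unadjusted p under 0.05, and 0 with slide as a block, with 279. Array weights called 6515, slides 1 and 2 alone 105, and the other fits 0. So 560 genes passed with both marrows, and for no gene was the difference between the marrows past the threshold. On simulated data the interaction fit called 3% of the genes changed 4-fold and 0% of those changed 2-fold. The lack of calls therefore does not show that the responses were alike.

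By camera 8 lists differed in their treatment effect, with no member past the threshold. The medians given for them are those of the difference in change of each gene, KO minus WT marrow. Matrix proteases (median 1.29, adjusted p = 0.00198), fibroblast and matrix genes (1.11, adjusted p = 0.00526), tuft cell markers (1.02, adjusted p = 0.0205), T and NK cell markers (0.95, adjusted p = 0.0205) and antigen presentation markers (1.48, adjusted p = 0.0205) had the more positive change with KO marrow, each with adjusted p = 0.564 with an estimated correlation. Proliferation genes (-0.38, adjusted p = 6.73e-05) and xenobiotic genes (-0.24, adjusted p = 0.0453), both with adjusted p = 0.564 with an estimated correlation, and fatty acid oxidation genes (-0.13, adjusted p = 0.0397, but adjusted p = 0.511 with an estimated correlation) had the more negative change. Blocked by slide, the proliferation (-0.69), protease (0.56), fibroblast (1.05) and tuft lists (1.05) passed in the same direction, and the antigen presentation (0.36), T and NK cell (0.02), fatty acid oxidation (-0.17) and xenobiotic lists (-0.05) did not. Goblet cell genes (0.46, adjusted p = 2.99e-05), interferon-stimulated genes (0.47, adjusted p = 0.00135) and antimicrobial genes (0.47, adjusted p = 0.00806) passed in that fit and not without the block. There 0 lists passed with an estimated correlation. With normexp 9 lists passed, 9 higher and 0 lower, against 5 higher and 3 lower here. Of the 8 lists, 7 lost the call without at least 1 array, proliferation genes being the exception. The number of lists was 4 without KO_untreated 3, 5 without WT_AOMDSS 3 or KO_AOMDSS 2, 13 without WT_AOMDSS 2 and 14 without WT_untreated 3 or KO_untreated 2.

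The authors' deposited table lists 2506 probes, each differing by at least 1.0001 log2 between its KO-marrow columns. Of the probes in the authors' deposited table, 1276 were higher and 1230 lower in treated than in untreated mice with KO marrow, and 2438 (97.3%) had the same sign in the WT-marrow columns. Of those in the authors' deposited table, 147 differed at least 2-fold between the treated columns and 424 between the untreated columns. Values of the authors' deposited table and group means computed from the arrays had r = 0.996, with a median absolute difference of 0.0094 log2. Of the 744 genes called with KO marrow, 718 had their probe in the authors' deposited table, while 6620 probes of the arrays differed at least 2-fold between the KO-marrow groups.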

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

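The tests of slide and dim spots for the excess of lower genes, and of correlated genes within a list, were chosen after the result was seen, the slide test having been changed from the sign of the change to the side of the median of all genes, and the test without the dim array WT_AOMDSS 3 and the splits were chosen before.

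The effect of AOM and DSS differed between KO and WT marrow for 8 gene lists, by the test of the interaction itself. The difference in the change, KO minus WT marrow, was taken for each gene, and its median over the genes of a list is given. This median need not equal the difference between the list medians of the marrows. The median difference was 1.29 for matrix proteases and their inhibitors, 1.11 for fibroblast and matrix genes and 1.02 for tuft cell markers. It was 0.95 for T and NK cell markers and 1.48 for antigen presentation and dendritic cell markers. It was -0.38 for proliferation genes, -0.13 for fatty acid oxidation genes and -0.24 for xenobiotic genes. With an estimated correlation 0 of the 8 passed camera, and 0 single genes passed limma, with 799 at an unadjusted p under 0.05. Of the 8, 4 passed with slide as a block in the same direction, the protease (0.56), fibroblast (1.05), tuft (1.05) and proliferation (-0.69) lists. Any difference between the marrows stays a hypothesis, since 55 of 100 drawn splits of the arrays shifted at least 8 lists and the highest other split shifted 22.

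With WT marrow 2395 genes were lower and 844 higher after treatment. With slide as a block the median of all genes moved from -0.244 to 0.47. Relative to it 93.6% of the genes called higher stayed above (median 1.72 before and 1.15 after). That share met the bar set against a slide difference as their whole source. It cannot decide the question, since these genes were picked for high values in a fit of the same arrays. The share that such picking alone would give was not computed. Spots near background are argued against as the whole source, since lower calls made up 65.5% among probes well above background on all arrays. A slide difference stays open for the genes called lower as well. Of these, 57.0% kept their sign, few enough to count for the slides by the first form of the test. A share of 78.2% stayed below the median of all genes, which does not decide it. Their own median relative to that of all genes went from -2.35 to -0.63, and no slide held both WT-marrow groups. In untreated mice with KO marrow, the array on slide 1 lay above those on slide 2 by a median of 0.352 over all genes. All WT_untreated arrays lay on slide 1, so a slide difference in that direction would make genes look lower after treatment. With 1 such array, slide and mouse cannot be told apart. Scaling bears on the excess as well, as quantile normalization gave 2396 lower and 2287 higher calls, and an effect of the treatment itself remains among the open explanations.

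In treated mice 9 lists differed between the marrows while 0 genes passed limma (189 at an unadjusted p under 0.05). Genes of a list rising and falling together between mice may account for this, since 1 of the 9 lists, the goblet cell genes, passed with the correlation estimated from the arrays. The dim array WT_AOMDSS 3 may also contribute, as 2 of the 9 kept their call and direction without it. Both explanations stay open, and a donor difference stays open beside them, with no list past the threshold within both slides.

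The 6 arrays of a comparison of 2 groups split in only 10 ways, too few for a share under 0.05. For the treatment effect with WT marrow the real split called 3239 genes, the highest other 11, and 1 of 10 splits called as many. With KO marrow it called 744, the highest other 0, and 1 of 10 called as many. With WT marrow the real split alone also parts slide 1 from slides 2 and 3, so its count cannot tell treatment from slide. For the donors, the real and the highest other split called 0 genes both in treated and in untreated mice (10 of 10). For gene lists the real split and the highest other shifted 15 and 16 with WT marrow (3 of 10 splits as large) and 17 and 20 with KO marrow (3 of 10). For the donors they shifted 9 and 17 in treated mice (6 of 10) and 8 and 18 in untreated mice (10 of 10). In the treatment comparisons every other split still holds unequal numbers of treated arrays on its sides. Part of a treatment effect stays in it, so these counts do not show how many lists would shift without treatment. For the interaction 100 of 200 possible splits were drawn, and for its lists chance is not excluded. A real count of 0 genes is matched by any split, here all 100, so the splits say nothing about it, and the same holds for the donors. Of the drawn splits 4 called any gene, and 1, with arrays of slides 1 and 3 alone on one side, called 5812, for a reason that was not tested. The slides alone do not account for it, since the 8 other drawn splits with those slides on one side called at most 56, and 6 of them 0.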

How the results depend on the processing

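Slides 1 and 2 alone, the within-slide fits, slide block with array weights, symbols only and the median signal for normexp were chosen after seeing the data. Where a count moved by over 1.5 times the cause was not tested, except that fits of fewer arrays or genes have less to work with. The treatment count with WT marrow (3239) was 834 with normexp, 1929 for probes well above background on all arrays, 11798 with array weights, 54 with array weights and slide block, 1320 with only the arrays compared and 128 with slide block. With KO marrow (744) it was 5038 with array weights, 1721 with slide block, 1322 with scan day block and 263 on slides 1 and 2 alone. The donor count in treated mice (0 in limma) was 330 on slides 1 and 2 alone and 562 within slide 2, and in untreated mice (0 in limma) 2 with normexp, Fam110a and AK016682, and 10606 with array weights. The interaction (0 in limma) had 6515 with array weights and 105 on slides 1 and 2 alone. Array weights gave WT_AOMDSS 3 a weight of 0.137. They gave KO_untreated 1 a weight of 0.265, against 3.076 and 2.601 for KO_untreated 2 and 3. KO_untreated 1 was the KO-marrow array on the slide of the WT_untreated arrays. So these weights set the donor comparison in untreated mice mostly between slides 2 and 1. Shared calls (560) were 330 with normexp, 2576 with array weights, 53 with array weights and slide block, 320 with only the arrays compared, 127 with slide block, 902 with scan day block and 199 on slides 1 and 2 alone. The r of 0.718 changed under no alternative by as much as its leave-one-array-out SE of 0.28. That bar was wide and could hardly be crossed. It left little room for a rise, and it was built from the fits without an array, where r was 0.461 to 0.806. With slide as a block r was 0.879. With an estimated correlation 6 lists shifted with WT marrow, 11 with KO marrow, 1 for the donors in treated mice, 1 in untreated mice and 0 for the interaction. Within slide 3, 4 lists differed between donors, quantile normalization left 3 lists for the donors in untreated mice and 5 for the interaction, and the interaction had 13 lists with probes well above background on all arrays and 5 with array weights. All other alternatives kept these counts within 1.5 times.

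Leaving out each array in turn gave 471 to 7617 calls with WT marrow, 247 to 1246 with KO marrow, 0 to 1682 for the donors in untreated mice (1682 without KO_untreated 1) and 234 to 910 shared calls, with 4 to 11 lists for the donors in treated mice, 7 to 16 in untreated mice and 4 to 14 for the interaction. The lowest and highest counts with WT marrow were without WT_untreated 1 and without WT_AOMDSS 3, and with KO marrow without KO_untreated 3 and without WT_AOMDSS 3, which also gave the lowest and highest shared count. Muc1 ranged from -1.02 to 0.003 with WT marrow and from -0.076 to 0.95 for the donors in treated mice, both turning without WT_AOMDSS 3. For the donors in treated mice the median of interferon-stimulated genes ranged from -0.18 to 0.72 (turned without KO_AOMDSS 2), of smooth muscle markers from -2.16 to 0.41 and of adipocyte markers from -1.17 to -0.18, the test of both turning without WT_AOMDSS 2.

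Other directions that turned, with the cause not tested, were these. With WT marrow, normexp gave 0.56 for Muc1, 0.22 for Slc22a2, 0.64 for Slc51a, 0.12 for Lor and 0.22 for Ugt1a1, and the mean of a gene's probes gave 0.52 for Muc1 and -0.065 for Pdgfra. Slide block gave 0.32 for Nrxn3, 0.10 for Nt5c1b, 0.41 for Flt3, 0.58 for Zbtb46, 0.42 for Tpsb2 and 0.11 for Slc4a1, and with array weights as well 0.39 for Zbtb46 and 0.043 for Tpsb2. For the lists with WT marrow, the interferon median was 0.50 with slide block and 0.49 with array weights as well, and the endoplasmic reticulum stress median was 0.52 and 0.63 in these fits, -0.024 with normexp and 0.22 on slides 1 and 2 alone, where the test against all other genes turned even if the median did not. For the donors in treated mice Muc1 was at -0.43 with normexp and -0.013 with array weights, and in untreated mice at 0.051 with the mean of its probes. For proliferation genes the median for the donors in treated mice was -0.20 with normexp, where the test against all other genes turned and the median did not. The other list medians for the donors in treated mice were -0.51 for tuft cell markers with normexp, -0.012 for interferon-stimulated genes with array weights, -0.061 for fibroblast genes within slide 3, and 0.25 for smooth muscle markers both within slide 2 and on slides 1 and 2 alone. For the interaction they were 0.14 for fatty acid oxidation and 0.011 for xenobiotic genes with normexp, and 0.069 for xenobiotic genes on slides 1 and 2 alone.

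Whether the replicate numbers pair the mice is not settled. Deviations of same-numbered arrays from their group means correlated at -0.385 to 0.514 over 18 pairs, with 7 over 0.1. Those of other numbers were at -0.489 to 0.463 over 36 pairs, with 19 over 0.1. In treated mice same-numbered arrays of the 2 marrows, which shared a slide, correlated at 0.418, 0.308 and 0.514. Other numbers on slide 3 gave 0.122 and 0.149. In untreated mice the same-numbered values were 0.424, -0.143 and 0.415. With the replicate number as a block, 2312 and 710 genes passed for the treatment effect with WT and KO marrow, 0 in the other 3 comparisons by limma, and 517 were shared. Signals near background limit KO_untreated 2, with 58.44% of gene probes well above background, and WT_AOMDSS 3, with 64.58% and the lowest 75th percentile, 153.2 units.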

Other observations

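The tests of slide and of epithelial loss for Dbp, those of Ddx3y and Uty, and the genes of the first 2 paragraphs, were chosen after their values were seen, and the set of other clock genes was chosen after Dbp and Nr1d1 were seen but before its own values were.

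Other genes on the lists changed with both marrows. Pfkfb3, a driver of glycolysis, rose by 3.17 ± 0.48 with WT marrow (adjusted p = 0.00438 in limma) and by 4.17 ± 0.48 with KO marrow (adjusted p = 0.00075), and with slide as a block by 2.84 (adjusted p = 0.16) and 3.75 (adjusted p = 0.00631). Vcam1, an adhesion molecule of activated endothelium, rose by 2.24 ± 0.60 and 2.89 ± 0.60, with 3.79 (adjusted p = 0.117) and 3.81 (adjusted p = 0.0102) with slide as a block. Il5ra, the interleukin-5 receptor of eosinophils, rose at least 6.34-fold and at least 9.33-fold, with an adjusted p of 0.152 and 0.00708 with slide as a block. Ly6d rose with KO marrow too, by 4.82 ± 0.71, and Tac1 with WT marrow, by 4.86 ± 0.76, with 3.23 with slide as a block (adjusted p = 0.0803). Jchain rose with WT marrow by 2.33 ± 0.41, with 1.43 with slide as a block (adjusted p = 0.324).

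Among stem cell and Wnt target genes, Myc (1.95 ± 0.32, 2.21 with slide as a block, adjusted p = 0.0925) and Ephb2 (1.06 ± 0.31, 0.95 with slide as a block, adjusted p = 0.298) rose with WT marrow, while with KO marrow Sp5 rose (2.99 ± 0.74) and Smoc2 fell (-1.75 ± 0.34). The list median was 0.18 and 0.12, and neither passed (adjusted p = 0.12 and 0.674), though with slide as a block it did with WT marrow (adjusted p = 0.0418, but adjusted p = 0.0538 with an estimated correlation). Whether Myc, Ephb2, Sp5 and Smoc2 differed between the marrows was tested by the interaction, which passed for no gene.

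Dbp and Nr1d1 are both driven by the circadian clock. Dbp was among the 5 largest falls named with each marrow, Nr1d1 among those named with KO marrow only. Over both marrows, with slide as a block, Dbp changed by -5.14 ± 0.5 (95% interval -6.25 to -4.04) and Nr1d1 by -4.09 ± 0.68 (-5.57 to -2.61). Of 8 other clock genes that peak near Dbp, 4 fell with WT marrow (Nr1d2, Tef, Per3 and Ciart) and 3 with KO marrow (Nr1d2, Tef and Ciart), with medians of -2.36 and -1.89, and with slide as a block 0 and 4 passed in limma (medians -1.59 and -1.4). That Dbp interval, ending at -4.04, met the bar set against the slides as the whole source. It also met the bar set against a loss of epithelial cells. Without the block, absorptive colonocyte markers had medians of -1.13 and -1.31 and lower quartiles of -2.19 and -1.95. The epithelial gene Epcam changed by 0.42 and 0.06. Neither test decides its question, since Dbp was picked for its large fall in a fit of the same arrays. The fall that such picking alone would give was not computed. A clock phase that differed between treated and untreated mice may also lie behind the falls of Dbp and Nr1d1. The hour at which the mice were killed is not given in the sources used here. Arntl, 1 of 5 genes that peak opposite to Dbp, rose past the threshold with WT marrow (1.34 ± 0.31, 0.19 with slide as a block). The medians of the 5 were 0.37 with WT and 0.95 with KO marrow (0.42 and 0.31 with slide as a block). They do not decide it, since a shifted phase called for medians over 0.5 with both. The test of epithelial loss chosen beforehand used the same medians and was undecided, since under 0 with at least 1 marrow would have counted for it and over 0.5 with both against it.

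Among sex-linked genes, measured on every array, Eif2s3y was at -3.13 ± 0.51 in the 6 treated and -4.95 ± 1.11 in the 6 untreated mice (SD), a difference of 1.82 (exact permutation test, two-sided, p = 0.00866, adjusted p = 0.0216 over 5 genes), and was well above background on 6 and 4 arrays. The difference was 3.14 ± 0.88 with slide as a block (95% interval 1.21 to 5.07), and on slide 2 the means were -3.01 and -5.79 with 2 mice each. Kdm5d was well above background on 5 treated and 0 untreated arrays (exact permutation p = 0.0152, adjusted p = 0.0253) and Ddx3y on 4 and 0 (exact permutation p = 0.00649, adjusted p = 0.0216), so no size of these differences is given. On slide 2, with 2 mice each, the treated mean of both genes was the higher. The permutation test takes no account of slide. Slide 1 held untreated and slide 3 treated mice alone, so the test cannot tell treatment from slide. Uty, also Y-linked, was well above background on 0 of the 12 arrays and did not differ past the threshold (exact permutation p = 0.392, adjusted p = 0.392). Xist, well above background on all 12, differed by -0.81 (exact permutation p = 0.119, adjusted p = 0.149), with means on slide 2 of -0.31 in treated and -0.39 in untreated mice. The sex of the mice and of the marrow donors is not given in the sources used here.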
